A study of Caenorhabditis elegans with 8 samples.

How the data were processed

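RNA from whole synchronized populations of wild-type C. elegans N2 at day 1, 6 or 12 of adulthood was extracted with Trizol, labelled with biotin and hybridised to Affymetrix C. elegans Gene 1.1 ST arrays, per the labels. The deposited values, 29317 probes by 8 arrays, were read as log2 signal, since they ran from 0.68 to 13.23 with none below 0. The normalization method, the software and the log base of the authors are not given in the sources used here, so the base was inferred from that range. The values were not centred per gene, and no detection calls accompany them. A probe table paired 26281 probes with exactly 1 gene symbol, 480 with several and 2556 with none. The 26761 probes with at least 1 symbol were tested, and each of 26128 genes was represented by its brightest probe, a choice that mattered for 138 genes with more than 1. Intensity gives no counts, so the number of arrays limits the precision.

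Groups were the 3 ages, with 3, 3 and 2 arrays, and the comparisons were day 6 against day 1, day 12 against day 1 and day 12 against day 6. A linear model with a mean per day was fitted to all 8 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with defaults, two-sided), so that the days shared an estimate of the spread with 5 residual and 5.07 prior degrees of freedom. P values were adjusted by Benjamini-Hochberg over the 26761 probes, a call was an adjusted p under 0.05, and calls with an absolute log2 difference of at least 1 were also counted. The 45 gene lists were tested in the 3 comparisons with camera at a preset inter-gene correlation of 0.01, adjusted over all 135 tests, beside camera with an estimated correlation and fry. Among the lists, markers of oocytes and eggshell, germline, sperm, embryos, molting and larval cuticle, males, muscle, neurons, intestine and hypodermis described tissues and stages that whole-animal samples hold. The 45 lists, the comparisons, their tests by limma, camera and fry and most alternative settings were fixed before the data were examined, and tests added later are named as such where they are reported.

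Named genes were, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among probes with exactly 1 symbol, with arrays of the 2 days not overlapping and a mean above the 25th percentile of probes in at least 1 of the days. For each gene list described, up to 6 members with the largest absolute difference were eligible, and vit-1 to vit-6, sod-3, hsp-16.2, daf-16 and lgg-1 were always included. Alternatives were an intensity trend with robust hyperparameters, quantile normalization, median centring, filters on dim probes, all 29317 probes, the arrays of the 2 days alone, array weights, each array left out, the replicate number as a block, a minimum change of 1.2-fold with treat, and the mean of a gene's probes. Cyclic loess normalization was added after a shift that depended on brightness was seen. The fit was tested on simulated data over 5 draws, with 200 of 26761 probes changed per draw by a log2 of 0.5, 1 or 2. At a change of 1 it recovered 74.9% (day 6 against day 1), 55.2% (day 12 against day 1) and 59.1% (day 12 against day 6). At 0.5 it recovered 3.28%, 2.09% and 1.79% in the same order. False calls made up 8.07%, 6.80% and 5.69% of the calls. Fewer probes were changed in a draw than were called in the data, which makes the adjusted threshold stricter, so these shares may not carry over. Probes without a symbol were left out of the comparisons because no gene could be named for them, and they are described separately.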

Results

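Transcript levels were measured on 8 Affymetrix C. elegans Gene 1.1 ST arrays, each hybridised with RNA from a whole synchronized population of wild-type N2 worms. The populations had reached day 1 (3 arrays), day 6 (3 arrays) or day 12 (2 arrays) of adulthood at 20 °C on OP50 E. coli. The replicates are named biological in the labels, and nothing further states whether they were separate cultures. Array medians lay between 2.3 and 2.4 on the log2 scale, and 63.2% of the tested probes had a mean under 3, a level treated here as dim. Across probes, Pearson's r was 0.984 to 0.990 between arrays of the same day, 0.973 to 0.982 between day 6 and day 1, 0.958 to 0.968 between day 12 and day 6, and 0.941 to 0.952 between day 12 and day 1. Probes are not independent replicates, and the number of arrays limits the precision of every value. The labels give no batch or processing date, so a batch that followed the days cannot be told apart from age.

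**Figure D1:**
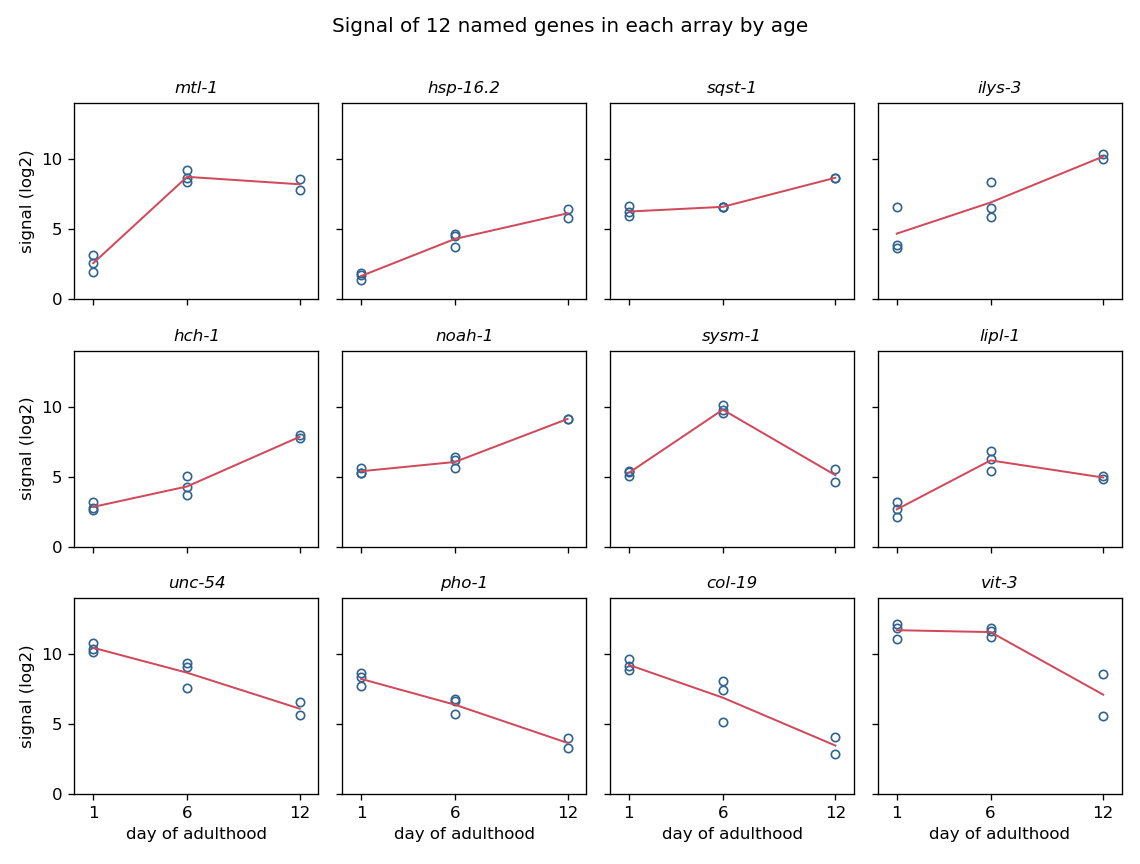
Log2 signal of 12 named genes by day of adulthood (circles, single arrays; the line joins the day means). mtl-1 rose from 2.57 ± 0.61 to 8.74 ± 0.42 from day 1 to day 6, and unc-54 fell from 10.45 ± 0.32 to 6.10 ± 0.68 from day 1 to day 12 (mean ± SD).

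The first question was what differed between populations at day 6 and day 1 of adulthood. The metallothionein gene mtl-1 rose from 2.57 ± 0.61 to 8.74 ± 0.42 (mean ± SD of the log2 signal, n = 3 and 3), starting near the floor of the signal (adjusted p = 2.56e-05). The median log2 difference was -1.07 over muscle sarcomere genes, -0.61 over intestine genes and 0.50 over insulin/DAF-16 responsive genes. The daf-16 gene itself, which encodes the FOXO transcription factor, had a log2 difference of 0.02 ± 0.18 (SE) and was not called. The 6 vitellogenin genes, which encode yolk proteins, were not called, with differences from -0.55 for vit-1 to 0.41 for vit-5.

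Values in parentheses here and in the following comparisons are log2 differences ± SE, later day minus earlier day, and the largest differences are those measured among genes that met the naming rule. A day mean under 3 is near the floor of the signal, so a difference from or to such a level is read as a lower bound and has no rank. Between day 6 and day 1 this covers mtl-1, dct-8, C18D11.6, asm-3 and F21C10.9 and, in the lists, lipl-1, col-73, dod-3, hsp-16.2, nlp-34, cyp-34A2 and tbx-8. Besides mtl-1, genes with the largest rises included T22B7.7 (5.46 ± 0.20), dct-8 (4.82 ± 0.31), sysm-1 (4.51 ± 0.24) and dhs-26 (4.47 ± 0.26), of which dhs-26 encodes a short-chain dehydrogenase. Others were C18D11.6 (4.15 ± 0.29), scl-2 (4.1 ± 0.25) and F56D6.9 (4.06 ± 0.22), where scl-2 encodes an SCP-like extracellular protein, the acid sphingomyelinase gene asm-3 (3.95 ± 0.37) and the lysozyme gene lys-7 (3.70 ± 0.31). The largest falls that held in every fit with an array left out were in the chemoreceptor gene sri-40 (-3.04 ± 0.44), the collagen gene col-155 (-2.78 ± 0.29) and Y54G2A.45 (-2.51 ± 0.40). Others that fell were the nuclear hormone receptor gene nhr-114 (-2.44 ± 0.29), Y50D4B.4 (-2.35 ± 0.26) and the methionine sulfoxide reductase gene msra-1 (-2.26 ± 0.36). Adjusted p was at most 0.00998 for these genes, and in each the arrays of the 2 days did not overlap, as the naming rule required and as chance gives in 10% of genes. The acyl-CoA dehydrogenase gene acdh-2 (-2.66 ± 0.50), F21C10.9 (-2.48 ± 0.41), grd-3 (-2.36 ± 0.44) and col-142 (-2.22 ± 0.41) were also called lower. Without day 1 replicate 1 the calls of acdh-2, grd-3 and col-142 were lost (adjusted p = 0.0649, 0.0569 and 0.0508), as they were without day 1 replicate 2 (0.0587, 0.0603 and 0.0606). The call of acdh-2 was also lost without day 6 replicate 3 (adjusted p = 0.0513), and that of F21C10.9 without day 6 replicate 1 (adjusted p = 0.0529).

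In the muscle sarcomere list, of 34 measured, 0 rose, 17 fell and 17 were not called, against 0 and 27 adjusted over the list alone. The muscle sarcomere list had a camera adjusted p of 6.34e-23, and adjusted p = 0.227 with an estimated correlation. The myosin regulatory light chain gene mlc-1 (-1.46 ± 0.21) and the troponin T gene tnt-3 (-1.40 ± 0.20) fell, and the troponin T gene tnt-2 had a log2 difference of -1.80 ± 0.59 and was not called. In the intestine list, of 24 measured, 0 rose, 7 fell and 17 were not called, against 3 and 13 adjusted over the list alone. The intestine list had a camera adjusted p of 5.89e-06, and adjusted p = 0.227 with an estimated correlation. Those that fell included the oligopeptide transporter gene pept-1 (-1.90 ± 0.26), the microvillar actin gene act-5 (-1.60 ± 0.22) and the intermediate filament gene ifb-2 (-1.56 ± 0.24). Lists of energy metabolism were lower too: in glycolysis 0 rose and 5 fell of 19 measured, or 0 and 5 adjusted over the list alone. The glycolysis list had a camera adjusted p of 0.00024, and adjusted p = 0.227 with an estimated correlation. In the tricarboxylic acid and glyoxylate cycle list 0 rose and 4 fell of 26 measured, or 0 and 4 adjusted over the list alone. That list also holds PEP carboxykinase, pyruvate carboxylase and pyruvate dehydrogenase genes. The tricarboxylic acid and glyoxylate cycle list had a camera adjusted p of 6.86e-07, and adjusted p = 0.227 with an estimated correlation. In the mitochondrial respiratory chain 0 rose and 2 fell of 40 measured, or 0 and 6 adjusted over the list alone. The mitochondrial respiratory chain list had a camera adjusted p of 1.13e-09, and adjusted p = 0.242 with an estimated correlation. In lipid binding and beta-oxidation 0 rose and 10 fell of 51 measured, or 3 and 15 adjusted over the list alone, with acdh-9 (-1.57 ± 0.24) among the falls. The lipid binding and beta-oxidation list had a camera adjusted p of 1e-04, and adjusted p = 0.242 with an estimated correlation. In the V-ATPase and lysosomal protease list, which also holds lipase (lipl) and lmp genes, 5 rose and 10 fell of 59 measured. Adjusted over the list alone, 8 rose and 27 fell. The rises included the lipase genes lipl-1 (3.50 ± 0.35), lipl-2 and lipl-5 and the aspartyl protease gene asp-4. The cathepsin B family gene cpr-9 (-1.12 ± 0.16) was among the falls. The V-ATPase and lysosomal protease list had a camera adjusted p of 0.000108, and adjusted p = 0.249 with an estimated correlation. Of the cuticle collagen genes 4 rose and 8 fell of 151 measured, or 8 and 18 adjusted over the list alone, with col-73 (3.28 ± 0.43) among the rises, and the list was not called. The collagen list had a camera adjusted p of 0.0841, and adjusted p = 0.529 with an estimated correlation.

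In the insulin/DAF-16 responsive list, of 27 measured, 10 rose, 1 fell and 16 were not called, against 13 and 1 adjusted over the list alone. The insulin/DAF-16 responsive list had a camera adjusted p of 6.61e-08, and adjusted p = 0.227 with an estimated correlation. Besides mtl-1 and lys-7, the long noncoding RNA gene tts-1 (2.87 ± 0.21), dod-3 (2.82 ± 0.24) and the small heat shock gene hsp-16.2 (2.65 ± 0.26) rose, while the superoxide dismutase gene sod-3 had a log2 difference of 0.23 ± 0.16 and was not called. The small heat shock list as a whole was not called, with 1 higher and 2 lower of 10 measured (camera adjusted p = 0.784). The Atg8 family gene lgg-1, of the autophagy list, had a difference of 0.27 ± 0.17 and was not called: in that list 1 rose and 0 fell of 28 measured, or 8 and 0 adjusted over the list alone. The autophagy list had a camera adjusted p of 5.89e-06, and adjusted p = 0.227 with an estimated correlation. Among antimicrobial and lysozyme genes 15 rose, 1 fell and 103 were not called, with 23 and 5 adjusted over the list alone, including nlp-34 (3.43 ± 0.46), cnc-7 (3.12 ± 0.37) and thn-2 (2.66 ± 0.17), and the list was not called. The antimicrobial and lysozyme list had a camera adjusted p of 0.0553, and adjusted p = 0.368 with an estimated correlation. Of the cytochrome P450 genes 9 rose and 1 fell of 73 measured, or 12 and 4 adjusted over the list alone, including cyp-34A9 (2.14 ± 0.28), cyp-37A1 (1.89 ± 0.20) and cyp-34A2 (1.86 ± 0.21). The cytochrome P450 list had a camera adjusted p of 0.0167, and adjusted p = 0.242 with an estimated correlation. Without day 1 replicate 2 this list was no longer called (adjusted p = 0.06). In the embryo list 5 rose and 0 fell of 32 measured, or 7 and 0 adjusted over the list alone, with the zinc finger gene ztf-11 (1.38 ± 0.15) and the T-box gene tbx-8 (1.01 ± 0.15) among the rises. The embryo list had a camera adjusted p of 0.000301, and adjusted p = 0.227 with an estimated correlation. The germline list was higher, with syp-1 (0.92 ± 0.14), a synaptonemal complex gene, called: 1 rose and 0 fell of 34 measured, or 1 and 0 adjusted over the list alone. The germline list had a camera adjusted p of 0.000632, and adjusted p = 0.35 with an estimated correlation. The oocyte and eggshell list was higher as well: 1 rose and 0 fell of 26 measured, or 1 and 0 adjusted over the list alone. The median log2 differences of the germline and the oocyte and eggshell lists were 0.25 and 0.17, against 0.12 over all probes above the dim level. They lay at percentiles 98.86 and 96.12 among 10000 lists of equally bright genes. The oocyte and eggshell list had a camera adjusted p of 0.00146, and adjusted p = 0.377 with an estimated correlation.

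By limma, 1029 of 26761 probes were called at an adjusted p under 0.05, 584 higher and 445 lower, and 530 of them (284 higher, 246 lower) had an absolute log2 difference of at least 1. With quantile normalization 438 were higher and 545 lower, and with cyclic loess, chosen after the data were seen, 403 were higher and 600 lower, so the balance of directions turned with the scaling. It also turned without day 1 replicate 1, with 312 higher and 355 lower. The count fell to 281 without day 6 replicate 1, 425 without day 6 replicate 3, 670 without day 6 replicate 2, 649 without day 1 replicate 2 and 667 without day 1 replicate 1. By camera, 26 of 45 gene lists were called, 11 up and 15 down, and 0 with an estimated correlation, where 11 of those 26 had an unadjusted p under 0.05 and fry called 20 of the 45.

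The comparison of day 12 with day 1 spans the widest interval of ages. The body wall myosin heavy chain gene unc-54 fell from 10.45 ± 0.32 to 6.10 ± 0.68 (mean ± SD of the log2 signal, n = 3 at day 1 and 2 at day 12; adjusted p = 0.000153). The adult cuticle collagen gene col-19 fell from 9.23 ± 0.39 to 3.46 ± 0.90 (adjusted p = 0.000335). The small heat shock gene hsp-16.2 rose from 1.65 ± 0.25 to 6.13 ± 0.46 (adjusted p = 7.78e-06), starting near the floor of the signal. The small heat shock list as a whole was not called, with 3 higher and 3 lower of 10 measured (camera adjusted p = 0.952). The median log2 difference was -1.69 over muscle sarcomere genes, -0.79 over intestine genes and -0.64 over glycolysis genes. It was 0.56 over autophagy genes, 0.59 over histone genes and 0.44 over embryo genes.

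Genes with the largest rises from day 1 to day 12 included C18D11.6 (7.89 ± 0.32), nlp-34 (5.83 ± 0.52), Y65B4BL.1 (5.82 ± 0.34) and T26H5.9 (5.73 ± 0.56), of which nlp-34 encodes a neuropeptide-like antimicrobial protein. Others were T23E7.6 (5.66 ± 0.25), mtl-1 (5.64 ± 0.36) and H39E23.3 (5.62 ± 0.73), the invertebrate-type lysozyme gene ilys-3 (5.51 ± 0.86), dct-8 (5.41 ± 0.35) and the C-type lectin gene clec-266 (5.36 ± 0.36). Collagen genes made up most of the largest falls, with col-80 (-6.03 ± 0.81), col-160 (-5.79 ± 0.83), col-19 (-5.76 ± 0.71) and col-179 (-5.67 ± 0.71). Others were col-140 (-5.65 ± 0.70), col-159 (-5.62 ± 0.97) and col-8 (-5.57 ± 0.75), and outside the collagens bcf-1 (-6.08 ± 0.68) and epic-2 (-5.60 ± 0.75). Adjusted p was at most 0.00275 for these genes. The SE rests on a spread shared by the days, which can hide a wide one at day 12. For bcf-1 the SD was 0.067 at day 1 and 2.199 between the 2 day 12 arrays, so the size of its fall is uncertain. Between the day 12 arrays the SD was 1.157 to 1.466 for col-80, col-160, col-140, epic-2 and col-8. The col-93 gene was also called lower (-6.71 ± 1.49, adjusted p = 0.0125), whose call was lost without day 12 replicate 1 (adjusted p = 0.0695) and without day 12 replicate 2 (adjusted p = 0.101). Levels near the floor make these values lower bounds without a rank for C18D11.6, nlp-34, Y65B4BL.1, mtl-1, H39E23.3, dct-8 and hsp-16.2, dim at day 1, and col-80, col-179, col-159 and col-93, dim at day 12. In the lists they do so for acox-1.5, cpr-2, hch-1, tbx-8, fbn-1, irg-2, spp-23 and sod-3. Of the 6 vitellogenin genes, which encode yolk proteins, vit-1 (-4.16 ± 0.54), vit-3 (-4.60 ± 0.68) and vit-4 (-4.18 ± 0.66) fell, the last by 2.66 without day 12 replicate 2. The SD between the day 12 arrays was 1.67, 2.12 and 2.14 for these genes, while vit-2 (-0.42 ± 0.18), vit-5 (-0.31 ± 0.21) and vit-6 (-0.53 ± 0.16) were not called. In the yolk list as a whole 0 rose and 3 fell of 6 measured, or 0 and 4 adjusted over the list alone, and whether probes separate near-identical copies, here and among hsp-16 genes, is uncertain. The yolk protein list had a camera adjusted p of 0.000108, and adjusted p = 0.255 with an estimated correlation.

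In the muscle sarcomere list, of 34 measured, 0 rose, 20 fell and 14 were not called, against 1 and 21 adjusted over the list alone, with a median of -1.69. The muscle sarcomere list had a camera adjusted p of 1.08e-16, and adjusted p = 0.242 with an estimated correlation. Besides unc-54, the troponin T gene tnt-2 (-5.18 ± 0.66), the regulatory light chain genes mlc-1 (-3.49 ± 0.24) and mlc-2 (-3.0 ± 0.29), the troponin I gene unc-27 (-3.38 ± 0.26) and the paramyosin gene unc-15 (-3.04 ± 0.32) fell. In the intestine list, of 24 measured, 3 rose, 12 fell and 9 were not called, against 3 and 15 adjusted over the list alone: the acid phosphatase gene pho-1 (-4.57 ± 0.37), the desaturase gene fat-7 (-3.55 ± 0.61), ifb-2 (-3.05 ± 0.27) and act-5 (-3.02 ± 0.25) fell, and the aquaporin gene aqp-2 (2.47 ± 0.15) rose. The intestine list had a camera adjusted p of 4.62e-06, and adjusted p = 0.227 with an estimated correlation. Among cuticle collagens 6 rose and 35 fell of 151 measured, or 7 and 37 adjusted over the list alone. The collagen list had a camera adjusted p of 9.08e-05, and adjusted p = 0.274 with an estimated correlation. In glycolysis 0 rose and 11 fell of 19 measured, or 0 and 12 adjusted over the list alone, with the glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 (-1.75 ± 0.20) and gpd-3 (-1.52 ± 0.22) among the falls. The glycolysis list had a camera adjusted p of 2.7e-08, and adjusted p = 0.227 with an estimated correlation. In the tricarboxylic acid and glyoxylate cycle list 0 rose and 12 fell of 26 measured, or 0 and 19 adjusted over the list alone. Among the falls were the malate dehydrogenase gene mdh-2 (-1.27 ± 0.20) and, from outside these cycles, the PEP carboxykinase gene pck-1 (-2.64 ± 0.20). The tricarboxylic acid and glyoxylate cycle list had a camera adjusted p of 2.19e-09, and adjusted p = 0.227 with an estimated correlation. In fatty acid synthesis and desaturation 1 rose and 8 fell of 21 measured, or 1 and 8 adjusted over the list alone, with the elongase genes elo-2 (-2.58 ± 0.24), elo-6 (-2.5 ± 0.15) and elo-5 (-2.19 ± 0.17). The fatty acid synthesis and desaturation list had a camera adjusted p of 0.00314, and adjusted p = 0.331 with an estimated correlation. In lipid binding and beta-oxidation 3 rose and 18 fell of 51 measured, or 5 and 20 adjusted over the list alone, with acdh-1 (-4.24 ± 0.28) and acox-1.5 (-3.19 ± 0.22). The lipid binding and beta-oxidation list had a camera adjusted p of 6.87e-06, and adjusted p = 0.227 with an estimated correlation. In the V-ATPase and lysosomal protease list, with its lipase genes, 3 rose and 25 fell of 59 measured, or 7 and 30 adjusted over the list alone. The aspartyl protease genes asp-14 (-3.57 ± 0.36) and asp-13 (-3.50 ± 0.18) fell and the cathepsin B family gene cpr-2 (3.76 ± 0.25) rose. The V-ATPase and lysosomal protease list had a camera adjusted p of 9.1e-09, and adjusted p = 0.227 with an estimated correlation.

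**Figure D2:**
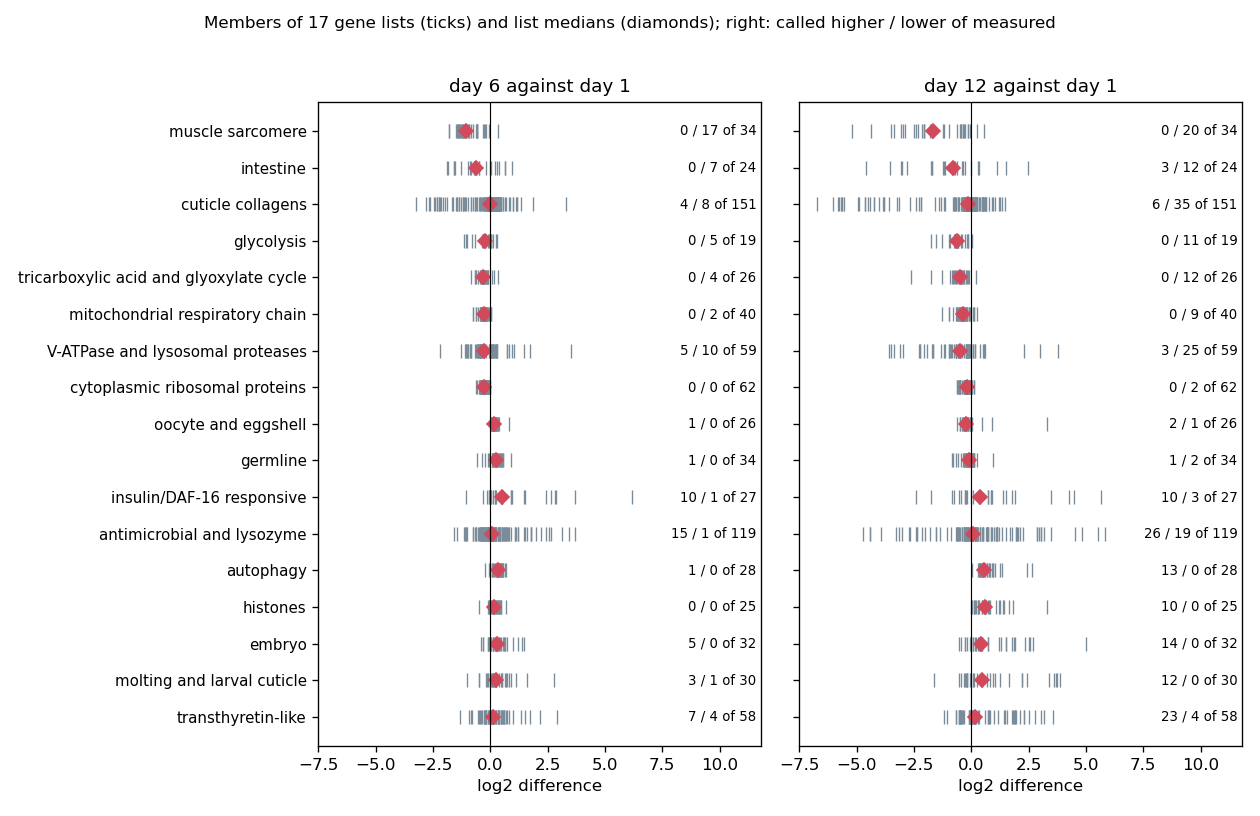
Log2 differences of the members (ticks) and their medians (diamonds) for 17 gene lists, day 6 against day 1 (left) and day 12 against day 1 (right), with the numbers of members called higher and lower of those measured. In the muscle sarcomere list 0 members rose and 17 of 34 fell at day 6, and 0 rose and 20 of 34 fell at day 12.

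In the autophagy list, of 28 measured, 13 rose, 0 fell and 15 were not called, against 20 and 0 adjusted over the list alone: the adapter gene epg-2 (2.65 ± 0.20), the p62 homologue sqst-1 (2.41 ± 0.20) and the Atg8 family gene lgg-1 (2.38-fold, adjusted p = 0.00131) rose. The autophagy list had a camera adjusted p of 3.4e-10, and adjusted p = 0.227 with an estimated correlation. In the histone list 10 rose and 0 fell of 25 measured, or 14 and 0 adjusted over the list alone, with the linker histone gene his-24 (3.28 ± 0.28) and with his-39 (1.80 ± 0.17) and his-31 (1.64 ± 0.20), whose near-identical copies make the gene of origin uncertain. The histone list had a camera adjusted p of 9.52e-08, and adjusted p = 0.242 with an estimated correlation. In the embryo list, of 32 measured, 14 rose, 0 fell and 18 were not called, against 15 and 0 adjusted over the list alone: the hatching enzyme gene hch-1 (5.0 ± 0.33), the T-box genes tbx-8 (2.71 ± 0.17) and tbx-38 (2.53 ± 0.29) and the epidermal fate gene elt-1 (1.92 ± 0.20) rose. The embryo list had a camera adjusted p of 2.19e-06, and adjusted p = 0.227 with an estimated correlation. In the molting and larval cuticle list 12 rose and 0 fell of 30 measured, or 12 and 0 adjusted over the list alone, with the lipocalin gene lpr-3 (3.88 ± 0.22), the precuticle genes noah-1 (3.73 ± 0.23) and noah-2 (3.60 ± 0.16) and the fibrillin-related gene fbn-1 (3.38 ± 0.19). The molting and larval cuticle list had a camera adjusted p of 9.95e-05, and adjusted p = 0.227 with an estimated correlation. The oocyte and eggshell list was not called: 2 rose and 1 fell of 26 measured, or 2 and 1 adjusted over the list alone, with the caveolin gene cav-1 (3.32 ± 0.21) among the rises. The oocyte and eggshell list had a camera adjusted p of 0.0541, and adjusted p = 0.544 with an estimated correlation. Antimicrobial and lysozyme genes moved both ways and the list was not called: 26 rose, 19 fell and 74 were not called, with 31 and 23 adjusted over the list alone, with irg-2 (4.82 ± 0.33) and ilys-2 (4.53 ± 0.49) higher and the saposin-like genes spp-17 (-4.72 ± 0.38) and spp-23 (-4.40 ± 0.53) lower. The antimicrobial and lysozyme list had a camera adjusted p of 0.634, and adjusted p = 0.785 with an estimated correlation. Of the insulin/DAF-16 responsive genes 10 rose and 3 fell of 27 measured, or 12 and 5 adjusted over the list alone, with tts-1 (4.24 ± 0.24) higher and lys-8 (-2.39 ± 0.17) lower, while daf-16 and sod-3 had differences of 0.09 ± 0.20 and -0.53 ± 0.18 and were not called. The insulin/DAF-16 responsive list had a camera adjusted p of 0.0369, and adjusted p = 0.331 with an estimated correlation. That list was no longer called with quantile normalization (adjusted p = 0.0529), cyclic loess (0.0683), the brighter probes alone (0.289), without day 1 replicate 1 (0.0543) or without day 12 replicate 2 (0.115).

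By limma, 3773 of 26761 probes were called between day 12 and day 1, 2564 higher and 1209 lower, and 2228 of them (1504 higher, 724 lower) had an absolute log2 difference of at least 1. With quantile normalization 1963 were higher and 1636 lower, and with cyclic loess 2139 were higher and 1584 lower. Day 12 had 2 arrays, and the count fell to 2454 without day 12 replicate 2. By camera, 24 of 45 gene lists were called, 8 up and 16 down, and 0 with an estimated correlation, where 10 of those 24 had an unadjusted p under 0.05 and fry called 28 of the 45.

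The comparison of day 12 with day 6 covers the later of the intervals. The bZIP transcription factor gene ces-2 rose from 3.47 ± 0.82 to 7.78 ± 0.43 (mean ± SD of the log2 signal, n = 3 at day 6 and 2 at day 12; adjusted p = 0.000201). The aspartyl protease gene asp-14 fell from 8.56 ± 0.39 to 4.04 ± 1.00 (adjusted p = 4.19e-05). The list medians were -0.42 for the muscle sarcomere, -0.63 for the intestine, 0.32 for autophagy and 0.30 for embryo genes. The small heat shock gene hsp-16.2 rose by 1.83 ± 0.29 on the log2 scale (adjusted p = 0.00252). Its list was not called, with 2 higher and 0 lower of 10 measured (camera adjusted p = 0.691).

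Genes with the largest rises from day 6 to day 12 included Y46H3A.5 (4.91 ± 0.16), Y65B4BL.1 (4.69 ± 0.34), ilys-2 (4.52 ± 0.49) and C27H5.6 (4.47 ± 0.38), of which ilys-2 encodes an invertebrate-type lysozyme. With ces-2 (4.31 ± 0.45) came F43C1.7 (4.1 ± 0.35), R03H10.6 (4.08 ± 0.18) and cutl-16 (3.97 ± 0.22), and F19B10.13 (3.95 ± 0.22) and F32H2.6 (3.94 ± 0.31), where cutl-16 is a cuticlin-like gene. Genes with the largest falls included C32H11.4 (-4.96 ± 0.35), sysm-1 (-4.68 ± 0.27) and asp-14 (-4.53 ± 0.36), F55G11.2 (-4.43 ± 0.22), the cathepsin A homologue ctsa-1.2 (-4.41 ± 0.36) and the saposin-like genes spp-4 (-4.23 ± 0.24) and spp-17 (-4.19 ± 0.38). Adjusted p was at most 0.00024 for these genes. Lower bounds without a rank, for a level near the floor, are those of Y46H3A.5, C27H5.6, F19B10.13 and F55G11.2 and, in the lists, of col-73, cpr-2, fbn-1, ins-8 and sod-3. The yolk protein genes vit-1 (-3.60 ± 0.54), vit-3 (-4.47 ± 0.68) and vit-4 (-4.30 ± 0.66) and bcf-1 (-4.43 ± 0.68) fell too, and without day 12 replicate 2 the differences of vit-3, vit-4 and bcf-1 were -2.97, -2.79 and -2.87. In the yolk list 0 rose and 4 fell of 6 measured, or 0 and 6 adjusted over the list alone, and the vit-2 and vit-5 differences of -0.47 ± 0.18 and -0.71 ± 0.21 were not called. The yolk protein list had a camera adjusted p of 7.52e-06, and adjusted p = 0.242 with an estimated correlation. The call of vit-6 (-0.59 ± 0.16, adjusted p = 0.0457) was lost without day 1 replicate 1 (adjusted p = 0.0569), day 6 replicate 1, 2 or 3 (0.1, 0.122 and 0.121) or day 12 replicate 1 or 2 (0.0795 and 0.276).

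In the muscle sarcomere list, of 34 measured, 0 rose, 10 fell and 24 were not called, against 0 and 12 adjusted over the list alone, with unc-27 (-2.13 ± 0.26), mlc-1 (-2.03 ± 0.24) and mlc-2 (-1.79 ± 0.29) among the falls. The muscle sarcomere list had a camera adjusted p of 0.000103, and adjusted p = 0.436 with an estimated correlation (fry adjusted p = 0.0972). In the intestine list 2 rose and 9 fell of 24 measured, or 2 and 12 adjusted over the list alone: pho-1 (-2.73 ± 0.37) and act-5 (-1.42 ± 0.25) fell and aqp-2 (3.36 ± 0.15) rose. The intestine list had a camera adjusted p of 0.00276, and adjusted p = 0.286 with an estimated correlation (fry adjusted p = 0.126). Among cuticle collagens 4 rose and 23 fell of 151 measured, or 5 and 25 adjusted over the list alone, with col-73 (-3.64 ± 0.48) among the falls. The collagen list had a camera adjusted p of 5.63e-05, and adjusted p = 0.271 with an estimated correlation. In the V-ATPase and lysosomal protease list, with its lipase genes, 2 rose and 12 fell of 59 measured, or 2 and 15 adjusted over the list alone. In it asp-13 (-3.66 ± 0.18) and vha-6 (-2.06 ± 0.23) fell and cpr-2 (3.52 ± 0.25) rose. The V-ATPase and lysosomal protease list had a camera adjusted p of 1.57e-05, and adjusted p = 0.242 with an estimated correlation. In fatty acid synthesis and desaturation 1 rose and 5 fell of 21 measured, or 1 and 6 adjusted over the list alone, with elo-6 (-1.80 ± 0.15) and elo-2 (-1.38 ± 0.24) lower and the fatty acid synthase gene fasn-1 (1.03 ± 0.17) higher. The fatty acid synthesis and desaturation list had a camera adjusted p of 0.004, and adjusted p = 0.331 with an estimated correlation. Among C-type lectins 7 rose and 27 fell of 240 measured, or 7 and 29 adjusted over the list alone, with clec-266 (3.30 ± 0.36) higher and clec-85 (-3.08 ± 0.31) lower. The C-type lectin list had a camera adjusted p of 0.00102, and adjusted p = 0.227 with an estimated correlation. The respiratory chain list was not called, with a median of -0.08: 0 rose and 0 fell of 40 measured, or 0 and 0 adjusted over the list alone. The mitochondrial respiratory chain list had a camera adjusted p of 0.166, and adjusted p = 0.695 with an estimated correlation.

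In the autophagy list 8 rose and 0 fell of 28 measured, or 9 and 0 adjusted over the list alone, with epg-2 (2.23 ± 0.20), sqst-1 (2.08 ± 0.20) and atg-2 (0.92 ± 0.15). The autophagy list had a camera adjusted p of 2.35e-05, and adjusted p = 0.242 with an estimated correlation. The lgg-1 difference of 0.98 ± 0.19 was called (adjusted p = 0.00848), but not without day 12 replicate 2 (adjusted p = 0.10). The difference of sod-3 was -0.76 ± 0.18 (adjusted p = 0.0241), and its call was lost without day 6 replicate 1 or 3 (adjusted p = 0.0798 and 0.0892) or day 12 replicate 1 or 2 (0.173 and 0.0502), while daf-16 (0.07 ± 0.20) was not called. In the embryo list 9 rose and 1 fell of 32 measured, or 13 and 1 adjusted over the list alone, with hch-1 (3.55 ± 0.33), tbx-38 (1.82 ± 0.29) and elt-1 (1.48 ± 0.20). The embryo list had a camera adjusted p of 5.05e-05, and adjusted p = 0.227 with an estimated correlation. In the histone list 9 rose and 0 fell of 25 measured, or 9 and 0 adjusted over the list alone, with his-24 (3.27 ± 0.28). The histone list had a camera adjusted p of 1.06e-06, and adjusted p = 0.255 with an estimated correlation. In the molting and larval cuticle list 10 rose and 0 fell of 30 measured, or 10 and 1 adjusted over the list alone, with lpr-3 (3.38 ± 0.22), fbn-1 (3.12 ± 0.19) and noah-1 (3.07 ± 0.23). The molting and larval cuticle list had a camera adjusted p of 0.00102, and adjusted p = 0.242 with an estimated correlation. The median of that list was -0.0045, its mean 0.62 and the direction of its test up, so median and mean differ in sign. Among insulin-like peptide genes 6 rose and 0 fell of 40 measured, or 10 and 0 adjusted over the list alone, with ins-8 (3.54 ± 0.23), ins-23 (2.33 ± 0.38) and ins-7 (2.16 ± 0.19). The insulin-like peptide list had a camera adjusted p of 0.00118, and adjusted p = 0.274 with an estimated correlation. The germline list was lower (0 rose and 1 fell of 34 measured, or 0 and 7 adjusted over the list alone), as was the oocyte and eggshell list (2 rose and 2 fell of 26 measured, or 2 and 10 adjusted over the list alone), in which cav-1 (2.5 ± 0.21) rose. The germline list had a camera adjusted p of 1.23e-06, and adjusted p = 0.256 with an estimated correlation. The oocyte and eggshell list had a camera adjusted p of 5.26e-05, and adjusted p = 0.306 with an estimated correlation.

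By limma, 2423 of 26761 probes were called between day 12 and day 6, 1703 higher and 720 lower, and 1610 of them (1150 higher, 460 lower) had an absolute log2 difference of at least 1. The count fell to 1371 without day 12 replicate 2. By camera, 27 of 45 gene lists were called, 10 up and 17 down, and 0 with an estimated correlation, where 4 of those 27 had an unadjusted p under 0.05 and fry called 23 of the 45.

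The intervals were then read together, gene by gene. Of the probes called in both, 115 rose in each interval, 120 fell in each, 107 rose by day 6 and fell by day 12, and 41 fell and then rose. Mean log2 levels at days 1, 6 and 12 show the courses: C18D11.6 rose throughout (2.27, 6.42 and 10.16), as did hsp-16.2 (1.65, 4.30 and 6.13). Among those that rose and then fell were sysm-1 (5.27, 9.78 and 5.10), asm-3 (2.66, 6.61 and 2.65) and F56D6.9 (3.12, 7.18 and 3.50). Independent lists of the same sizes would share 37.2, 12.0, 15.7 and 28.3 probes in these 4 classes, and the day 6 arrays enter both intervals with opposite signs. In 100 simulated draws of unchanged groups sharing those arrays, 0 probes at most were called the same way and 1 at most in opposite ways. Since a draw called at most 3 probes between day 12 and day 6, these overlaps were bound to be near 0 and do not show what sharing adds between long lists. With 1 day 6 array in one interval and the other 2 in the other, over 6 splits run after the data were seen, 9 to 49 probes rose in each interval, 1 to 103 fell in each, 19 to 52 rose and fell, and 0 to 12 fell and rose by limma. The first 3 counts were at least 4.28, 12.0 and 9.52 times the overlaps of independent lists and the last at most 1.16 times, with the estimate of the spread still shared. The 12.0 rests on 2 shared probes, from lists of 8 and 558. Such overlaps treat all 26761 probes as equally likely to be called. But the 14813 with a mean under 2.5 gave only 21 of the 584 higher and 19 of the 445 lower calls at day 6. These ratios therefore overstate the excess. The count of 383 probes changed in both intervals fell to 148 without day 6 replicate 1, 170 without day 6 replicate 3, 247 without day 6 replicate 2 and 229 without day 12 replicate 2.

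Against day 1, 368 probes were higher and 356 lower at both day 6 and day 12, 724 in all, where independent lists would share 56 and 20.1. mtl-1, dct-8 and nlp-34 were among those higher on both days, and msra-1, mlc-1 and act-5 among those lower. Both contrasts use the same 3 day 1 arrays, and part of the excess may come from that. In 100 simulated draws of unchanged groups with those arrays shared, at most 1 probe was called the same way, but a draw called at most 2 at day 12, so that count does not show what sharing adds. With 1 day 1 array in one contrast and the other 2 in the other, over 6 splits run after the data were seen, 48 to 199 probes were higher in both and 26 to 229 lower in both. These were 6.41 to 7.88 and 11.9 to 17.8 times the overlaps of independent lists, with the estimate of the spread still shared. Those overlaps again treat dim, rarely called probes like the others, so the ratios overstate the excess. The covariance of the log2 differences was 0.154, against 0.019 in the simulated draws. The count of 724 fell to 211 without day 6 replicate 1, 321 without day 6 replicate 3, 480 without day 6 replicate 2 and 448 without day 1 replicate 2.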

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

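The tests of a single lower share of muscle RNA and of hatched larvae were chosen only after the results were seen. Probes with no gene symbol, 2556 in all, lie outside the comparisons, and a fit over all probes gave calls among them. Between day 6 and day 1, 18 of them were higher and 93 lower, between day 12 and day 1, 92 and 156, and between day 12 and day 6, 75 and 40. These calls were 4.34%, 9.70% and 4.50% of the probes without a symbol, against 3.55%, 13.4% and 8.55% of those with one.

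In the muscle sarcomere list at day 12 against day 1, 0 rose, 20 fell and 14 were not called of 34 measured, with a median of -1.69. Its camera call was lost with an estimated correlation (adjusted p = 0.242). The falls were uneven: the 34 members had an SD of 1.37 around a mean of -1.59. A group of 17 body wall sarcomere members, formed after their values were seen, were all called lower, with a median of -2.43. Of the other 17 members 3 fell (myo-1, myo-2 and tnt-3) and 14 were not called, such as pat-3 (0.53) and act-2 (-0.35). Since the grouping followed the values, this split does not show that body wall genes fell more than other muscle genes. The list median was -1.92 after quantile normalization, which argues against scaling between arrays, and the median of -1.69 lay at percentile 0 among 10000 lists of equally bright genes, which argues against bright probes falling together. If 1 lower share of muscle RNA were the whole cause, the members would fall alike, but the body wall genes alone ran from -5.18 for tnt-2 to -1.17 for unc-89, and their SD of 1.06 was 3.25 times their root mean square SE of 0.33. Unequal response of probes could add to that spread. So could day 12 levels close to the floor, such as those of unc-22 (3.03) and myo-3 (3.04), though deb-1 fell by 1.23 to 6.36, away from it. The spread therefore does not settle whether a lower share was the whole cause, and a lower share as part of the cause stays open. A difference that belongs to age itself was not tested apart from these and also stays open, as a hypothesis.

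In the embryo list at day 12 against day 1, 14 rose, 0 fell and 18 were not called of 32 measured, and its camera call was lost with an estimated correlation (adjusted p = 0.227). The list median of 0.44 lay at percentile 99.78 among lists of equally bright genes, which argues against dim probes rising together. Embryos in the day 12 samples are a candidate explanation: a further 32 genes of embryonic neural and pharyngeal fate, chosen after the day 12 differences had been seen but before its own members were looked at, except nhr-25, which is also in the hypodermis list, had a median of 0.91 at percentile 100, with 17 called higher and 0 lower. Of the 32, 14 had a mean above the dim level, with a median of 1.91. That mean takes in the day 12 arrays, so a high day 12 level helps a gene to pass. An example is lim-6, with 2.91, 2.86 and 3.80 at days 1, 6 and 12. The median of 1.91 is therefore raised in part by the selection. The genes ceh-43, ham-1, nhr-25 and ceh-32 differed by 4.91, 3.84, 3.19 and 2.91, to day 12 levels of 8.44, 7.98, 6.62 and 6.42. But 15 of the list were not called, among them ceh-22 (-0.10), ceh-24 (0.07) and ceh-34 (-0.03), known from the pharynx, and cnd-1 (-0.11), unc-3 (-0.18) and ceh-36 (-0.01), known from neurons, all 6 under 3 on each day. The 17 called higher also included pha-4 (0.96), tbx-2 (0.97), unc-86 (2.16), ngn-1 (2.60), lin-32 (1.03) and sox-2 (2.54). Several that rose, such as nhr-25, egl-18, elt-6 and ceh-16, are also known from the epidermis, and a rise in the epidermis was not tested apart. For hatched larvae, 6 larval cuticle collagen genes had medians of 1.02 (day 6 against day 1), 0.35 (day 12 against day 1) and -0.56 (day 12 against day 6). With levels of 1.57 to 3.40 at day 12 these genes were near the floor of the signal, day 6 may itself hold larvae, and the collagen genes sqt-3 and dpy-3, called higher at day 12, were not among the 6, so they decide nothing. No value here separates embryos in the samples from larvae or from embryonic genes active in the tissues of old animals, so each stays open, and whether progeny were removed is not stated in the sources used here.

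A set of 107 probes rose by day 6 and fell again by day 12. Sharing of the day 6 arrays by both intervals might give such a pattern, but with different day 6 arrays in each interval 19 to 52 probes were still called in both, and the lowest ratio to the overlap of independent lists was 9.52. That ratio overstates the excess, since the overlap treats dim, rarely called probes as equally likely to be called. Neither an effect of age nor a handling difference at day 6 was tested, and both stay open, since the labels give no batch.

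The 6 arrays of day 1 and day 6 can be split in 10 ways, of which 1, the real split, gave 1029 calls, and the highest of the others gave 0 by limma, with 4514 probes at an unadjusted p under 0.05 in the real split and 775 to 1230 in the others. With 10 splits no share under 0.05 can be reached. Every other split put arrays of both days in each group, so a difference between the days widened the spread and lowered the calls. The contrast between the real split and the others is therefore no evidence for the calls.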

How the results depend on the processing

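The cyclic loess values were added only after the data had been seen. The counts called at day 6 against day 1, day 12 against day 1 and day 12 against day 6 were 1029, 3773 and 2423, and stayed within 1.5 times of these under the trend and robust prior, quantile normalization, centring, filters on dim probes, all probes, the 2 days alone, array weights and cyclic loess. With a minimum change of 1.2-fold, a stricter test by construction, they were 335, 2408 and 1562. Leaving out each array in turn gave 281 to 937, 2454 to 3519 and 1371 to 2568, with a lone day 12 array assumed to vary like the other days. The 724 probes changed the same way against day 1 ranged from 211 to 607, and the 383 changed in both intervals from 148 to 352, with fewer arrays in each fit. With the replicate number as a block, they were 786, 3244, 2081, 548 and 305, while between day 1 and day 6 residuals of equal replicate number correlated at -0.114 to -0.026 across probes and others at -0.049 to 0.078, so no array of these days correlated best with its own number, and day 12 was not examined. Of the 77 gene list calls, 0 held with an estimated correlation, where 11, 10 and 4 had an unadjusted p under 0.05 in the 3 comparisons. The cause of the loss was not tested, but a higher correlation is not needed for it. The cytosolic chaperone list between day 6 and day 1 had an estimated correlation of -0.0174, below the preset 0.01. Its unadjusted camera p was still 0.0206 with the estimate, against 0.00272 with the preset. For the cytochrome P450 list between day 6 and day 1 the estimate was 0.0112, close to the preset. Its unadjusted camera p still went from 0.00844 with the preset to 0.05 with the estimate. A list call lost with the estimate, here and above, is therefore no sign in itself of correlated members. The counts of list calls with an array left out were 72 to 81, with 77 under the block, 82 with quantile normalization, 84 with cyclic loess and 71 by fry. No list call and no call of a named gene reversed in any setting run: of 839 gene results, 23 calls were lost and 22 gained with quantile normalization, 18 and 22 with cyclic loess, and at least 712 kept their side of the threshold with any array left out, the fewest without day 12 replicate 2. Scaling moved the median difference of probes above the dim level from 0.12, 0.11 and -0.03 to 0.04, -0.02 and -0.07 (quantile) or 0.01, 0.00 and -0.02 (cyclic loess), and the cause was not tested. Signal over background limits dim probes: 63.2% of those tested had a mean under 3, near the floor of the signal.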

Other observations

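No test in this part was chosen only after its result was seen, apart from the enrichment of the genes that rose and fell again. Between day 12 and day 1, the glutathione S-transferase and UDP-glucuronosyltransferase lists were lower: of the glutathione S-transferases 1 rose and 13 fell of 47 measured, or 5 and 15 adjusted over the list alone, with gst-27 (-2.94 ± 0.18) and gst-4 (-2.25 ± 0.19) lower and gst-24 (3.0 ± 0.35) higher. The glutathione S-transferase list had a camera adjusted p of 0.00111, and adjusted p = 0.242 with an estimated correlation. Of the UDP-glucuronosyltransferases 3 rose and 12 fell of 67 measured, or 3 and 13 adjusted over the list alone, with ugt-22 (-3.34 ± 0.17) and ugt-12 (-3.33 ± 0.29) lower. The UDP-glucuronosyltransferase list had a camera adjusted p of 0.000103, and adjusted p = 0.274 with an estimated correlation. In the F-box and MATH/BTB list, which also holds Skp1-related (skr) genes, 86 rose and 5 fell of 438 measured, or 88 and 6 adjusted over the list alone, with fbxa-24 (4.12 ± 0.35) and fbxc-40 (3.73 ± 0.26) and the Skp1-related gene skr-9 (3.70 ± 0.26) higher. The F-box and MATH/BTB list had a camera adjusted p of 0.00022, and adjusted p = 0.249 with an estimated correlation. Of the transthyretin-like genes 23 rose and 4 fell of 58 measured, or 24 and 7 adjusted over the list alone, with ttr-26 (3.55 ± 0.23) and ttr-51 (3.18 ± 0.22) among the rises, a list median of 0.15 at percentile 94.88 among lists of equally bright genes, and a list call lost without day 12 replicate 2 (adjusted p = 0.0628). The transthyretin-like list had a camera adjusted p of 0.00146, and adjusted p = 0.465 with an estimated correlation. The insulin-like peptide genes ins-23 (3.74 ± 0.38), ins-8 (3.51 ± 0.23) and ins-7 (2.84 ± 0.19) rose, and the list was not called: 8 rose and 0 fell of 40 measured, or 9 and 0 adjusted over the list alone. The insulin-like peptide list had a camera adjusted p of 0.0661, and adjusted p = 0.465 with an estimated correlation. Levels under 3 on either day make the differences of fbxc-40, gst-24, gst-27, ins-8, ttr-26 and ugt-12 lower bounds.

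Markers of other stages and tissues at day 12 against day 1 were as follows: among sperm genes 4 rose and 1 fell of 71 measured, or 2 and 1 adjusted over the list alone, and among male genes 1 rose and 0 fell of 12 measured, or 1 and 0 adjusted over the list alone. The sperm list had a camera adjusted p of 0.236, and adjusted p = 0.65 with an estimated correlation. The male list had a camera adjusted p of 0.354, and adjusted p = 0.468 with an estimated correlation. Among neuron and synapse genes 5 rose and 4 fell of 37 measured, or 5 and 4 adjusted over the list alone, with the syntaxin gene unc-64 (1.19 ± 0.21) higher and bas-1 (-1.42 ± 0.17) lower. The neuron and synapse list had a camera adjusted p of 0.456, and adjusted p = 0.665 with an estimated correlation. Among hypodermis and seam genes 6 rose and 2 fell of 20 measured, or 7 and 2 adjusted over the list alone, with the chitinase gene cht-1 (4.40 ± 0.32) higher. The hypodermis and seam list had a camera adjusted p of 0.131, and adjusted p = 0.453 with an estimated correlation. Among germline genes 1 rose and 2 fell of 34 measured, or 1 and 2 adjusted over the list alone. The germline list had a camera adjusted p of 0.0553, and adjusted p = 0.545 with an estimated correlation. Between day 12 and day 6 the sperm list was called higher, with 10 up and 1 down of 71 measured. The neuron and synapse list was called higher there too, with 4 up and 1 down of 37 measured. Their camera adjusted p values were 0.00212 and 0.00259, and 0.331 and 0.242 with an estimated correlation. Their fry adjusted p values were 0.0587 and 0.0153. Between day 6 and day 1 both lists were called lower. Camera adjusted p was 0.0147 and 0.00347 there, and 0.402 and 0.242 with an estimated correlation. Fry adjusted p was 0.264 and 0.0372, so fry called the sperm list in neither of these comparisons. Of the 71 sperm genes, 16 had a mean above the dim level.

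Of the 85 genes above the dim level that rose by day 6 and fell by day 12, 4 were among 24 cytochrome P450 genes, 5 among 59 antimicrobial and lysozyme genes and 6 among 52 C-type lectins. One-sided Fisher's exact tests against the 9628 genes above that level gave adjusted p = 0.00118, 0.00246 and 0.000262 over the 45 lists. Against the 506 of those genes that were higher at day 6, with the same 85 genes, the adjusted p values were 0.192, 0.668 and 0.102 (unadjusted 0.00854, 0.0891 and 0.00227), so no enrichment beyond that rise was called.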
